A study of Pimephales promelas with 15 samples.

How the data were processed

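The series holds 15 libraries of pooled whole larvae, 5 per group, grouped by the exposure given in the labels. Per the labels' protocols, total RNA was extracted with a column kit, poly(A) RNA was selected from 250 ng, and strand-marking libraries were made. Per the submitters' processing notes, Trimmomatic 0.38, StringTie 1.3.4d and edgeR 3.26.5 were used. The aligner, genome build and annotation are not given in the sources used here, nor is whether counting used the strand, so antisense and overlapping genes cannot be told apart.

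The authors deposited 1 table of whole-number counts per ID and library, which was used as it stands. StringTie derives counts from coverage, so these counts may be estimates. The authors also deposited 2 tables of their own comparisons with solvent. Per the file headers, these hold a signed fold change, a log2 fold change, a log2 mean CPM, a p-value with its adjusted p-value, and an F score for each ID. They were used only for comparison.

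All 26150 IDs have the form of a scaffold prefix and a number. None (0) matched the 64593 genes of the reference table for assembly fPimPro1.hap1.1, and 0 of the 1376 symbols in the 39 gene lists fixed before the data were examined matched an ID. The planned tests of gene lists were therefore not run. The rule for named genes, fixed at the same time, asked for the largest changes among called genes that have a symbol, and so named none. In its place 2 IDs that rose and 2 that fell are printed, chosen after their values were seen (the largest fold at 100 ng/L in each of 2 prefix sets, and the IDs that fell), and the other called IDs are given by prefix.

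Counts were analysed in R 4.3.3 with edgeR 4.0.16. IDs were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and fitted with robust quasi-likelihood over all 15 libraries with group means only. Each contrast was tested with glmQLFTest, and Benjamini-Hochberg adjusted p below 0.05 was the threshold. CPM values are TMM-normalised. Folds are 2 to the power of the fitted log2 fold change. Sets of IDs sharing a prefix were compared by their share of counts on the log2 scale with exact two-sided permutation tests over 252 relabellings. These sets were chosen after the calls were seen, so their tests are not independent evidence of the change.

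On counts simulated for 100 ng/L against solvent, with 21734 IDs tested, the fit recovered 12% of 50 IDs changed 1.5-fold, 58% of 50 changed 2-fold, 84% of 50 changed 4-fold and 100% of 50 changed 50-fold. There were 5 false calls in that simulation and 0 calls where nothing was changed. The simulated libraries were drawn independently around 1 mean per group. They held no link between libraries of the same replicate number and no library set apart from its group, so recovery in the real counts may differ. No 2 libraries were identical, and log-CPM correlations within groups ran from 0.935 to 0.977. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples.

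The groups share replicate numbers 1 to 5. Deviations from the group means correlated between same-numbered libraries by 0.11 to 0.62 for 20 ng/L and solvent and by 0.23 to 0.39 for 100 ng/L and solvent, all above the 0.1 set as the limit for paired numbers. This pairing comes from the data, since the labels do not state one. Over all groups the mean was 0.27 for 15 same-numbered pairs and -0.07 for 60 others. Deviations from a group mean cancel out within the group, so the second mean nearly follows from the first. It adds no evidence of pairing. Fits with the replicate number as a block were run beside the unblocked ones.

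Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE factors, library size only, no filter, a filter of at least 1 CPM in 5 libraries, only the groups compared, the replicate block, non-robust estimation, stricter thresholds, and each library left out in turn. Those added after seeing the data left out solvent library 1 or all libraries numbered 1 with other settings, used quality weights in limma-voom, or used the filter that gives the ID set of the authors' tables (above 5 CPM in at least 4 of 14 libraries) with non-robust estimation. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.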

Results

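Whole fathead minnow larvae (Pimephales promelas), pooled within each sample, were profiled by poly(A) mRNA sequencing at 4 days post-hatch. Exposure to 17α-ethinylestradiol (EE2), a synthetic estrogen used in oral contraceptives, began within 6 hours of fertilization and ended 96 hours after hatching, in dishes with static renewal. A solvent control received 0.01% DMSO. The other groups received EE2 at nominal levels of 20 or 100 ng/L, and each of the 3 groups had 5 libraries. The titles of the EE2 samples give no DMSO level, so they do not show whether the groups were matched for solvent. Total gene counts per library ran from 32674182 to 73989987. Mean totals were 47572371 ± 9559353 (SD, n = 5) in solvent, 55108019 ± 16982039 (SD, n = 5) at 20 ng/L and 38385158 ± 6479044 (SD, n = 5) at 100 ng/L. Of 26150 gene identifiers (IDs), 21976 had enough counts to be tested. The files do not pair these IDs with gene names, so IDs are given as deposited and sets of IDs by their shared prefix, whose meaning the files do not state. Neighbouring IDs of one prefix can be copies of a gene or parts of 1 gene model that share reads, so their separate values are uncertain.

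The comparison of 20 ng/L EE2 with solvent asked which transcripts respond to the lower concentration. A set of 3 scaf36 IDs rose from near zero by between 241- and 357-fold (346- to 411-fold without solvent replicate 5). The most abundant of them, scaf36.44, went from 0.283 CPM ± 0.0739 (SD, n = 5) in solvent to 102 CPM ± 20.2 (SD, n = 5), a log2 fold change of 8.48 (SE 0.21, edgeR quasi-likelihood adjusted p = 1.03e-12). A second set, 5 scaf140 IDs, rose by between 90.3- and 194-fold, and by between 48- and 108-fold without replicate 5 of 20 ng/L. Within it scaf140.8 went from 0.749 CPM ± 0.398 (SD, n = 5) to 96.9 CPM ± 103 (SD, n = 5), a log2 fold change of 7.04 (SE 0.80, edgeR adjusted p = 6.25e-04; 6.24 without replicate 5 of 20 ng/L). The spread of scaf140.8 at 20 ng/L was as large as its mean, with libraries between 12.9 and 261.7 CPM, yet each lay above all 5 solvent libraries. The other 3 IDs called were 1 scaf62 ID (49.8-fold, or 32.1-fold without replicate 5 of 20 ng/L), 1 scaf15 ID (16.7-fold) and 1 scaf14 ID (2.32-fold).

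In all, 11 IDs rose and 0 fell at 20 ng/L at an edgeR adjusted p below 0.05. With an unadjusted edgeR p below 0.05 there were 141 IDs, where 1099 would be called by chance from uniform p-values. With the replicate block there were 276, and without solvent library 1 there were 333. The p-values were thus not uniform and ran high, so these counts do not show that no other ID changed. DESeq2 on all libraries called 16, 14 up and 2 down, among them the 11. By limma-voom 6 of the 11 IDs were called, and scaf140.8 was not (adjusted p = 0.739, against 1.17e-23 to 0.739 over the planned settings).

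At 100 ng/L EE2 against solvent, the same 11 IDs rose, and the scaf140 set stood out by its level. Its 5 IDs rose by between 1920- and 3660-fold, and scaf140.8 reached 2697 CPM ± 921 (SD, n = 5), a log2 fold change of 11.84 (SE 0.95, edgeR adjusted p = 5.57e-06). Together the 5 scaf140 IDs took 1.14% ± 0.257 (SD, n = 5) of all counts at 100 ng/L, 0.0662% ± 0.0688 (SD, n = 5) at 20 ng/L (0.0377% ± 0.0301, SD, n = 4, without its replicate 5) and 0.000474% ± 0.000152 (SD, n = 5) in solvent. The scaf36 set rose by between 186- and 353-fold (317- to 410-fold without solvent replicate 5), with scaf36.44 at 100.8 CPM ± 11.1 (SD, n = 5). The scaf62 ID rose 282-fold. A further 10 IDs rose that were not called at 20 ng/L. For 8 of them the fold changes lay between 1.58 and 35.1, and between 1.1 and 7.18 at 20 ng/L. The other 2, scaf178 IDs, had counts in 1 solvent library each, 11 counts in replicate 4 (245-fold) and 4 counts in replicate 3 (51.4-fold). Without that library, and against a floor of 3 counts over the other 4 solvent libraries, they were at least 715- and 59.6-fold higher. At 20 ng/L they were 31.2- and 5.7-fold higher (17.3- and 3.74-fold without replicate 5 of 20 ng/L; at least 90.5- and 6.23-fold against the same floor). The first of them had no overlap between the 20 ng/L and solvent libraries and missed the call there (edgeR adjusted p = 0.0747), but was called without replicate 4 of 20 ng/L (0.0351). Of the 10, 1 scaf13 ID lost its call without any 1 of 7 libraries, 1 scaf75 ID without any 1 of 5 and 1 scaf178 ID without any 1 of 3 (edgeR adjusted p from 0.0508 to 0.0971).

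**Figure D1:**
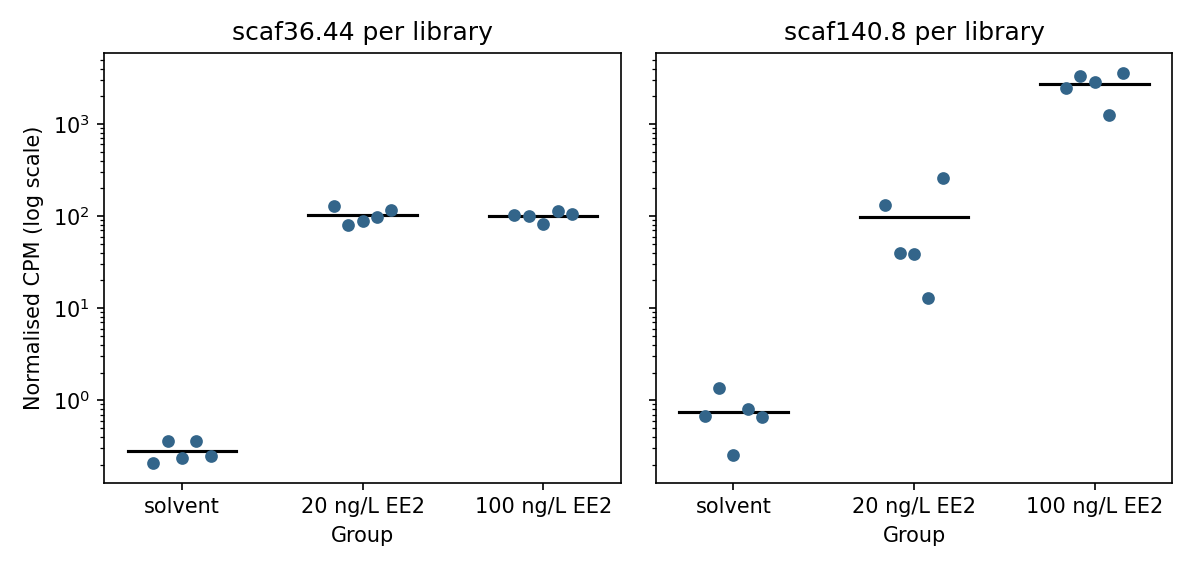
Normalised abundance (CPM, log axis) of scaf36.44 and scaf140.8 in each of the 15 libraries; points are libraries and bars are group means. scaf36.44 sits near 102 CPM at 20 ng/L and 100.8 CPM at 100 ng/L, while scaf140.8 has a mean of 96.9 CPM at 20 ng/L and 2697 CPM at 100 ng/L.

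By edgeR with all libraries, 2 IDs fell at 100 ng/L. On all libraries, 27 fell by DESeq2, 44 by limma-voom with quality weights, 4 with library size only and 1 by limma-voom. Levels of scaf17.139 fell from 11.8 CPM ± 4.01 (SD, n = 5) to 5.15 CPM ± 0.521 (SD, n = 5), a log2 fold change of -1.20 (SE 0.21, edgeR adjusted p = 0.0290). Levels of scaf10.101 fell from 99.8 CPM ± 26.8 (SD, n = 5) to 45.0 CPM ± 10.6 (SD, n = 5), a log2 fold change of -1.15 (SE 0.20, edgeR adjusted p = 0.0358). With the replicate number as a block, neither passed (edgeR adjusted p = 0.0799 for scaf17.139 and 0.123 for scaf10.101). Both lost the call without any 1 of 8 libraries, that is all of the 10 compared but solvent replicates 1 and 2 (edgeR adjusted p from 0.0687 to 0.118 for scaf17.139 and from 0.0563 to 0.157 for scaf10.101). Over the planned settings the adjusted p of scaf17.139 ranged from 2.73e-05 to 0.219 and that of scaf10.101 from 3.51e-05 to 0.198.

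The count at 100 ng/L was 23 IDs, 21 up and 2 down (edgeR adjusted p below 0.05). It rested on solvent library 1: without it the fit called 991 IDs, 453 up and 538 down, among them all 23. Without the libraries numbered 1 of every group the unblocked count was far lower (given below), so the rise did not depend on solvent library 1 alone. Scaled by library size only, that fit called 530 IDs, 185 up and 345 down. Leaving out any other solvent or 100 ng/L library gave between 18 and 25, and DESeq2 on all libraries called 60, 33 up and 27 down. In the authors' deposited table for 100 ng/L, 1143 of 15569 IDs had an adjusted p below 0.05, 488 up and 655 down. The log2 fold changes in the authors' deposited table differ by at most 4.8e-14 from a fit without solvent library 1, and by up to 1.1 from a fit with all 15 libraries. The same filter with all 15 libraries called 22 IDs. For 20 ng/L the authors' deposited table had 11 IDs with an adjusted p below 0.05, the same 11 as called here.

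**Figure D2:**
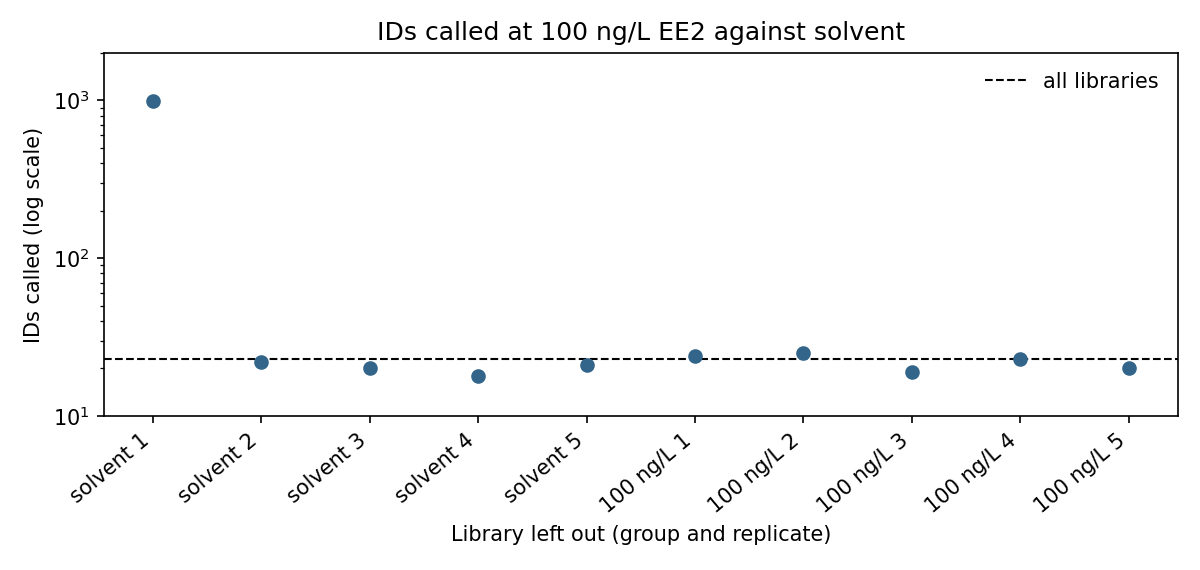
Number of IDs called at 100 ng/L EE2 against solvent (edgeR adjusted p below 0.05, log axis) when each solvent or 100 ng/L library was left out in turn; the dashed line is the count of 23 with all libraries. Leaving out solvent library 1 gave 991, and leaving out any other library gave between 18 and 25.

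The direct comparison of 100 with 20 ng/L asked whether the response grew with concentration. The scaf140 set did: its share of counts was 25.7-fold higher at 100 ng/L as a ratio of geometric means (exact two-sided permutation test, p = 0.00794, adjusted over 6 such tests 0.00953, n = 5 per group, higher in 5 of 5 libraries). The set was made of IDs already called, 3 of them in this comparison, so that p-value is no independent evidence of growth. It is also the smallest that 252 relabellings can give. The scaf36 set had a ratio of 0.984 (exact two-sided permutation test, p = 0.881, n = 5 per group). For scaf36.44 the 95% confidence interval of the log2 difference was -0.32 to 0.28. By ID, 6 rose and 0 fell at an edgeR adjusted p below 0.05, 3 of them in the scaf140 set and 1 each of scaf381, scaf8 and scaf10. The scaf10 ID did not grow from solvent upwards: it had 44.2 CPM ± 6.01 (SD, n = 5) in solvent, 32.4 CPM ± 3.35 (SD, n = 5) at 20 ng/L and 51.8 CPM ± 3.95 (SD, n = 5) at 100 ng/L, was not called against solvent (edgeR adjusted p = 0.880 and 0.622), and lost its call here without any 1 of the 10 libraries (0.0602 to 0.176). For scaf140.8 the log2 fold change was 4.80 (SE 0.70, adjusted p = 0.0225, against 8.76e-10 to 0.177 over the planned settings), or 5.60 without replicate 5 of 20 ng/L, and the call was lost without any 1 of 7 libraries (0.0514 to 0.112). The count fell to 0 without replicate 1, 2 or 3 of 20 ng/L or replicate 2, 3 or 5 of 100 ng/L, and to 2 without solvent library 1, while DESeq2 called 37, 18 up and 19 down. With only the 2 groups compared in the fit, 2 rose and 3 fell, and 2 of these 5 were among the 6.

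Both comparisons with solvent shared the same control libraries. All 11 IDs called at 20 ng/L were called at 100 ng/L in the same direction, against 0.0105 for independent lists. In 50 simulations of unchanged groups the overlap was 0, but at most 1 ID at 20 ng/L and 2 at 100 ng/L were called there, so this does not show how far shared controls raise the overlap of longer lists. With the solvent libraries divided between the comparisons, 5 to 10 IDs were called in both over 20 such divisions. Across all tested IDs, which are not independent replicates, the log2 fold changes had a correlation of 0.50 and a covariance of 0.061. Without the called IDs these were 0.31 and 0.027. The simulated unchanged groups gave 0.50 and 0.058 (covariances from 0.054 to 0.064), and the divided solvent libraries gave covariances from -0.078 to 0.039, or from -0.114 to 0.003 without the called IDs. The simulation held no link between same-numbered libraries of different groups, and the covariance without the called IDs lay below all simulated values, so the simulated value does not settle whether the fold changes shared more than their controls.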

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

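Of the tests below, those of mislabelling, of fold changes under library size alone and of total counts as a covariate were chosen after the result was seen, and the shuffled totals were added after the covariate count was known. Among 96 groups of 5 libraries examined for a library far from the others, 6 had one. By 1 in 20 that would be about 4.8 for independent groups with normally distributed values. IDs of one prefix are not independent, and a group with 4 libraries at 0 and 1 above it always has one. The 4.8 is thus no chance value for these groups. At 100 ng/L, replicate 5 had 4.25 CPM of scaf17.139 where the others had 5.21 to 5.58. Replicate 2 at 100 ng/L had 9.34 CPM of 1 scaf36 ID, with a gap to the nearest of the others of 0.838 of the group's range. The same library had 5.71 CPM of 1 scaf22 ID where the others had 0.231 to 0.784. Solvent library 1 had 2.24 CPM of the scaf381 ID where the others had 0.678 to 1.11. For 2 scaf178 IDs, 1 solvent library each had counts (0.198 CPM in replicate 4 and 0.0720 CPM in replicate 3) where the other 4 had 0.

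Without solvent library 1 the calls at 100 ng/L went from 23 to 991. Mislabelled or EE2-exposed larvae in that library are argued against by the scaf36 IDs, whose share of counts there was 0.285% of the mean at 20 ng/L. These IDs were chosen with that library in the fit, but all 3 were also called at 20 ng/L without it. Sampling depth is argued against too, since thinning the 14 libraries to the smallest total left at least 933 calls in 5 draws. The number depends on the scaling, with 530 calls under library size alone, below the limit set beforehand. Under library size alone all 991 IDs kept their direction, and the count still rose from 25 to 530. Over the 991 IDs the median absolute log2 fold change was 0.60 with composition scaling and 0.61 under library size alone. A change of scaling moves all log2 fold changes one way, so this median over rises and falls together cannot test the scaling as their source. Of the 464 IDs that lost the call, the 268 that rose went from a median of 0.395 to 0.373 (median SE 0.097 to 0.105). The 196 that fell went from 0.653 to 0.681 (median SE 0.166 to 0.176). For these 464 the fold changes kept most of their size in each direction. The scalings themselves differed little. With all 15 libraries the median log2 fold change at 100 ng/L over the tested IDs was -0.006 with composition scaling (TMM) and -0.046 with library size only. The choice between them thus did not make these fold changes. That follows from the small difference and tests no bias that both scalings share. On 4 lists of 1000 IDs chosen without it, solvent library 1 lay at 146% of the shift from solvent to 100 ng/L (139% to 152%). The other solvent libraries, when held out, lay at -9.13% to 45.1%. A difference other than EE2 may put solvent library 1 there. It was singled out because leaving it out raised the calls, so its position may partly follow from that choice. Replicates 1, 3, 4 and 5 of 100 ng/L lay at 87.1% to 119%, and replicate 2 at 53.1% to 66.5% over the lists. The 20 ng/L libraries lay at 11.4% to 51.2%. The 100 ng/L libraries helped choose the lists, so their own positions do not test which of them share the difference. On the first principal component, solvent library 1 (-28) lay near replicates 1, 4 and 5 (-36, -30.2 and -48.8). Replicate 3 (-4.32) lay nearer to replicate 2 (1.74).

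What sets solvent library 1 apart stays open. The first principal component followed log2 total counts across the 15 libraries (Pearson r = 0.58, permutation p = 0.024, adjusted 0.048; Spearman rho = 0.63, permutation p = 0.013, adjusted 0.027; 2 components examined), with r = 0.75 without the 2 libraries farthest from the median total, but within groups the pooled r was 0.42 (permutation p = 0.094), from 0.55 in solvent, 0.05 at 20 ng/L and 0.84 at 100 ng/L (n = 5 each). With log2 total counts as a covariate and solvent library 1 left out, 22 IDs were called. Over the 991 IDs the median absolute log2 fold change went from 0.60 to 0.53 and the median SE from 0.14 to 0.15. With the totals shuffled within groups the median count was 58 (22 to 991 over 20 fits, 1 of them as low as with the real totals), so a property that goes with the total count cannot be told apart from the effect of adding such a covariate, and why the calls ended was not tested.

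Other groupings of the same libraries bear on chance. At 20 ng/L, 2 of 100 splits gave as many IDs, the real one (11) included, with the highest other at 274. At 100 ng/L, 4 of 100 did, with 23 for the real split and 4452 for the highest other. For 100 against 20 ng/L, 1 of 100 did, with 6 and 2. Without solvent library 1, 2 of 100 did, with 991 and 1260. Each share is under 0.05, which counts against chance only if all splits are equally possible. The pairing of same-numbered libraries puts that in doubt for the comparisons with solvent. Leaving out solvent library 1 gave the largest count among the libraries left out in turn. The other splits were given no such choice, so the share without that library is no test of chance. The split with 4452 calls set solvent library 1 and 100 ng/L replicates 1, 3, 4 and 5 against the rest, which points to a structure of the samples. It parted 3 of the 5 same-numbered pairs. The other splits drawn that parted as many pairs as the real one numbered 12 at 20 ng/L, 15 at 100 ng/L and 14 without solvent library 1, too few for a share under 0.05. Their highest counts were 1, 0 and 1.

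A second pattern was 32 tested IDs at 0 in at least 3 libraries and at 100 or more counts in at least 3 others. EE2 exposure is argued against as the general source, since 2 of them had 100 or more counts in libraries of 1 exposure state only, where relabelling gave 3.02 on average; these 2 were themselves among the called IDs. Same-numbered libraries shared the on or off state in 62.9% of comparisons, above the relabelled range (mean 51.6%, upper limit 58%), so a genotype or other feature shared by libraries of 1 number may contribute. Over the 29 of these IDs outside scaf22 that have a neighbour, the median correlation with the most opposed neighbouring ID was -0.38. That lay just below the matched range (-0.36 to -0.10), with single IDs from -0.99 to 0.57. Reads moved between neighbouring gene models may therefore contribute as well, by a narrow margin for the median. Both stay open.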

How the results depend on the processing

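Settings that add a second change to leaving out solvent library 1, leave out all libraries numbered 1, or use quality weights or the authors' filter with no robust estimation were chosen after seeing the data. For named and called IDs no direction reversed in any planned setting. Of the 11 IDs called at 20 ng/L, 5 passed in all 19 planned settings, as did 17 of 23 at 100 ng/L and 0 of 6 between concentrations. At 20 ng/L the count of 11 was 11 to 12 over the libraries left out in turn and 11 with the replicate block, which kept all 11 IDs. It was 6 by limma-voom, 7 with quality weights, 17 by DESeq2 without solvent library 1, 6 without that library and with the replicate block, and 5 without all libraries numbered 1 and with the replicate block.

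At 100 ng/L the count of 23 ranged from 18 to 991 over the libraries left out in turn and was 25 with the replicate block, which kept 21. DESeq2 called 60 and quality weights 85. Without solvent library 1 it was 530 with library size only, 2314 with the replicate block and 2657 by DESeq2, and 1146 with the authors' filter and no robust estimation. Without all libraries numbered 1 it was 40, and 1031 with the replicate block. Without solvent library 1, library size only moved the split from 453 up and 538 down to 185 up and 345 down. Between concentrations the count of 6 ranged from 0 to 8 over the libraries left out, and was 0 at an adjusted p below 0.01. It was 37 by DESeq2, 574 by DESeq2 without solvent library 1, 18 with quality weights, and, without all libraries numbered 1, 0 without and 3 with the replicate block. With the replicate block on all libraries it was 12, of which 5 were shared; here same-numbered libraries correlated by 0.08 to 0.45, and 3 of 5 correlated best with their own number. The overlap of 11 fell to 5 or 6 where 2 solvent libraries served 20 ng/L and 3 served 100 ng/L, fewer controls by construction. Other than where stated, the cause was not tested. The gene list tests and their alternatives were not run, because no ID matched a symbol.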

Other observations

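The 11 IDs called at both concentrations differed in how they went on from 20 to 100 ng/L. For 5 of them, the 95% confidence interval of the log2 difference between 100 and 20 ng/L ended at 0.66 or below, which leaves out a further rise of 2-fold; they were the 3 scaf36 IDs, the scaf15 ID and the scaf14 ID. The scaf15 ID had 8.19 CPM ± 1.25 (SD, n = 5) at 20 ng/L and 8.04 CPM ± 0.202 (SD, n = 5) at 100 ng/L. The 5 scaf140 IDs instead differed by 11.1- to 27.8-fold between concentrations (20- to 48.4-fold without replicate 5 of 20 ng/L), with no overlap between the libraries of the 2 groups for any of the 5. The remaining one, the scaf62 ID, was 5.66-fold higher at 100 than at 20 ng/L (95% confidence interval 2.46 to 13, edgeR adjusted p = 0.451; 8.79-fold without replicate 5 of 20 ng/L), with up to 327.3 CPM at 20 ng/L and at least 324 CPM at 100 ng/L. Grouping by response was made after the values were seen.

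Replicate 5 at 20 ng/L had 261.7 CPM of scaf140.8 and replicate 4 had 12.9 CPM, while scaf36.44 in the same libraries had 116.5 and 97.2 CPM.

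One scaf22 ID had 47.7 to 71.2 CPM in 4 solvent libraries and 0.306 CPM in replicate 3. It had 0.446 to 0.722 CPM in the 20 ng/L libraries and 0.231 to 5.71 CPM in the 100 ng/L libraries, and was not called with all libraries (edgeR adjusted p = 0.0552 at 20 ng/L and 0.134 at 100 ng/L). Without solvent library 1 the edgeR adjusted p was 0.182 at 20 ng/L and 0.0366 at 100 ng/L, so it was then called at 100 ng/L. Without solvent replicate 3 it was called at both (5.91e-04 and 2.05e-03), and without replicate 2 of 100 ng/L it was called at 100 ng/L (0.0246). The authors' deposited table gives an adjusted p of 0.0279 at 100 ng/L. Another scaf22 ID, near it in the numbering, had 0 counts in 6 libraries and 100 or more in 9. That ID correlated by -0.74 with its most opposed neighbouring ID. The neighbour test above left scaf22 out, so whether reads moved between these gene models was not tested.

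A test fixed before its result was seen asked whether the 991 IDs called at 100 ng/L without solvent library 1 lie next to each other in the ID numbering. Of these, 107 had a called next-numbered ID, where 10000 random draws gave 84.8 on average and at most 132. The rule asked for more than every draw, so a grouping of called IDs along the numbering was not shown, nor is it excluded. Of 57 adjacent pairs, 33 (57.9%) went in the same direction, where 50.4% would be expected.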
